A study of Drosophila melanogaster with 4 samples.

How the data were processed

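Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for acetylated lysine 18 of histone H3 (H3K18ac) was carried out on wild-type Oregon-R Drosophila melanogaster embryos collected 14 to 16 h after egg laying, with an antibody lot that the labels call new. The series holds 4 samples, 2 ChIP libraries and 2 input libraries, numbered replicate 1 and 2 in each group. Per the labels' protocols, embryos were fixed in 1.8% formaldehyde before immunoprecipitation. Each input served as the control of the ChIP replicate with the same number, per the labels. The input libraries were not analysed here on their own, since the lists of enriched regions already set each ChIP library against its input.

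Each list gives a start, an end and a score for every enriched region, called a cluster here. Per the submitters' processing notes, Bowtie 0.12.7 was among the tools used. The region caller, its threshold and its read filters are not given in the sources used here. Per the file headers, coordinates are on FlyBase r5, and the sequence lengths used below were read from those headers. The authors deposited 1 list per ChIP replicate and 1 list for the series, whose name marks it as made from the set of replicates and which is called the combined list here. How the replicates were combined is not given in the sources used here. The score of each cluster is the authors' own value as deposited, with no stated scale, log base or background. Scores were therefore used to rank, filter or describe clusters within a list. Differences of score between chromosomes were taken within each list before they were averaged over the replicates, and their size has no stated unit.

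Cluster lists differ from read counts in how they can be compared. No read depth came with them, so the depth is unknown and no interval that needs reads could be given. A cluster absent from a list was not called, which does not show that the mark is absent. The combined list was made from the same libraries as the replicate lists, so its overlap with them is not independent evidence. Nothing in the labels says whether the replicates came from separate embryo collections, so the spread between them may be technical.

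Lists were read and compared in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9. Clusters of different lists were called shared when they had at least 1 bp in common. Chance sharing was measured by rotating the clusters of replicate 1 along each sequence by a random offset, 10000 times, and counting how often sharing was at least as high (a one-sided permutation test whose smallest p is 0.0001). On simulated lists the test found sharing in 2 of 2 list pairs with planted shared clusters, and in 5 of 60 pairs of independent lists at p 0.05. Simulated clusters were spread evenly along the arms, with 4000 drawn per list in planted pairs and 800 in independent pairs. The real clusters lie closer together, so this check does not give the false positive rate for these lists. Shares of clusters carry 95% exact Clopper-Pearson intervals, which cover counting error only and treat clusters as independent. Rank agreement of scores was tested with Spearman's rho and 100000 permutations, two-sided. Values per replicate are given with the mean and the SD over 2 replicates. Covered shares and scores were not tested between chromosome arms, apart from an interval on counts of high-scoring clusters on X. Arms of the same library are paired, and an exact two-sided paired permutation test over 2 replicates cannot give p below 0.5 (0.333 for 2 against 2 unpaired values).

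The comparisons between replicates, with the combined list and between X and autosomes, the rule for named regions and the alternatives listed below were fixed before the data were examined. Rotations by 50 to 500 kb and sharing of clusters on the major arms alone were added as alternatives after the lists had been examined. Several descriptions were also chosen then: sharing by score quartile and by length, the scores on X with their alternatives, the 1-Mb windows, the ends of the arms near the centromere and Fisher's exact test of cluster counts per arm. The rule named the 10 combined clusters with the highest score and the 5 longest among those overlapping a cluster in both replicates. It also named the 3 highest-scoring clusters of each replicate with no counterpart in the other, and the 3 longest stretches of the major arms without a combined cluster. Alternatives were the clusters scoring at or above the median of their list, merging of clusters within 1 kb, stricter overlaps, lists of equal number, major arms only for the number of clusters and the Jaccard index, other definitions of the X to autosome ratio, and leaving out each replicate. A gene table of FlyBase release 6 was at hand, but its coordinates are of another build than the clusters and no coordinates were converted. The planned placement of clusters at transcription start sites and at 16 gene lists was therefore not run, and clusters are named by position.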

Results

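H3K18ac was mapped by ChIP-seq in late wild-type Drosophila embryos, aged 14 to 16 h, a stage at which muscle, nervous system and cuticle are differentiating. H3K18ac is a histone acetylation mark found at active promoters and enhancers, laid down in flies by the acetyltransferase Nejire (CBP). The data comprised enriched clusters for 2 ChIP replicates, each called against its own input, and a combined list for the series. Replicate 1 held 4370 clusters covering 17.4 Mb, and replicate 2 held 4910 clusters covering 16.2 Mb. The combined list held 7536 clusters covering 29.7 Mb. Clusters covered 13.9% ± 0.680 (SD, n = 2) of the 6 major chromosome arms in the replicates and 24.6% in the combined list. Read depth was unknown for every library, so the lists could not be set beside their depth.

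The first comparison asked whether the 2 replicates marked the same places. They did so for most clusters: 3104 of 4370 clusters of replicate 1 (71.0%, 95% exact interval 69.7 to 72.4) overlapped a cluster of replicate 2, and 3592 of 4910 clusters of replicate 2 (73.2%, 71.9 to 74.4) overlapped one of replicate 1. Broad domains were shared most often. All 443 clusters of at least 8 kb in replicate 1 and all 346 in replicate 2 overlapped the other list, whereas 49.5% and 53.0% of clusters under 2 kb did. Clusters of 2 to 4 kb were shared in 78.7% and 85.2% of cases, and those of 4 to 8 kb in 96.7% and 99.4%.

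Over both lists 72.2% of clusters were shared, against a mean of 22.7% when replicate 1 was rotated along the chromosomes (one-sided permutation test, p = 0.0001, the smallest the 10000 rotations can give). The lists had 12.3 Mb in common, which was 70.6% of the bases of replicate 1 and 75.6% of those of replicate 2. The Jaccard index of covered bases was 57.5%, against 7.57% on average after rotation (same permutation test, p = 0.0001). Longer clusters also met the other list more often by chance, but over 1000 rotations the mean chance shares of replicate 1 were 18.7% under 2 kb, 21.2% at 2 to 4 kb, 27.7% at 4 to 8 kb and 41.4% at 8 kb or more, each below the observed share. A requirement of 50% reciprocal overlap lowered the share to 43.9% and the mean chance share to 4.77%.

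Sharing also differed with the authors' score. In replicate 1, 55.9% of clusters in the lowest score quartile and 92.9% of those in the highest were shared, and in replicate 2 these values were 57.0% and 93.9%. Score and length went together across clusters, with Spearman's rho of 0.73 in replicate 1 and 0.71 in replicate 2. Among clusters under 2 kb the order was the opposite. In replicate 1, 54.0% of those scoring below their median and 45.1% of those at or above it were shared (Fisher's exact test on clusters, two-sided, p = 0.000146). In replicate 2 these shares were 54.6% and 51.3%, a difference that did not pass the threshold (p = 0.121 in Fisher's exact test). In clusters of 2 to 8 kb the higher-scoring ones were shared more often, without a test, and from 8 kb all were shared. At 2 to 4 kb the shares below and at or above the median score were 74.9% and 82.6% in replicate 1 and 80.6% and 89.8% in replicate 2, and at 4 to 8 kb they were 95.3% and 98.1%, and 99.1% and 99.7%. At shared clusters of replicate 1, scores of the 2 lists ranked alike with a Spearman's rho of 0.60 over 3104 clusters (two-sided permutation test, p = 1e-05, the smallest the resamples can give). Where several clusters of replicate 2 overlapped, the highest of their scores was used. Over 1834 one to one pairs the rho was 0.57 (same permutation test, p = 1e-05). Clusters are not independent replicates, so the p-values of these permutation tests and of Fisher's exact test describe the lists and not the embryos.

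**Figure D1:**
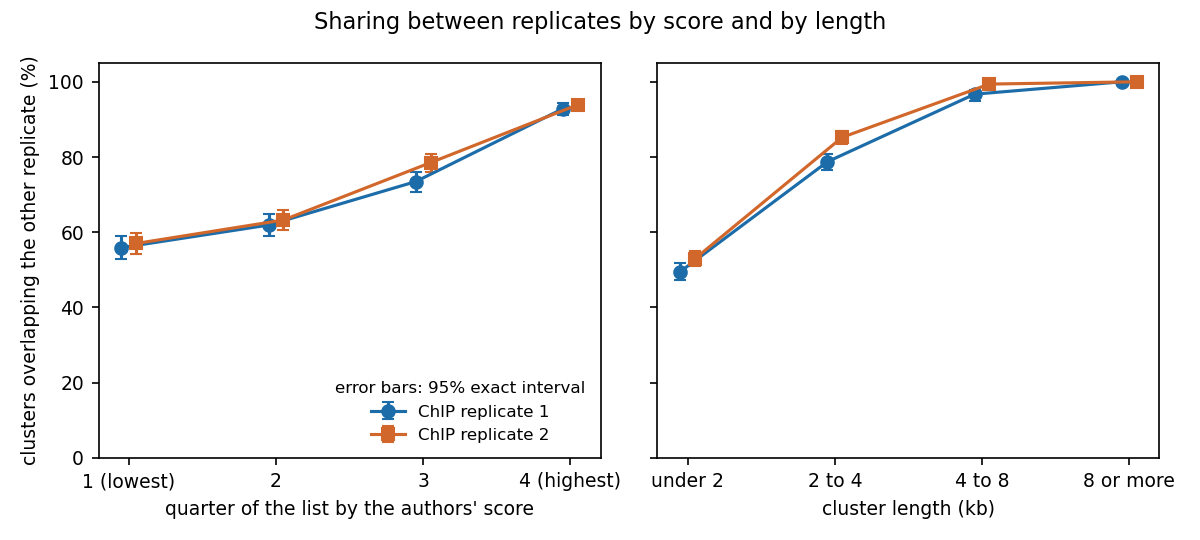
Share of clusters of each replicate (vertical axis, percent) that overlap a cluster of the other replicate, by quartile of the authors' score (left) and by cluster length in kb (right), with 95% exact intervals that cover counting error only. The share lies between 49.5% and 53.0% under 2 kb and is 100% from 8 kb in both replicates.

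Clusters without a counterpart were short. Their median length was 1652 bp in replicate 1 (1266 clusters) and 1594 bp in replicate 2 (1318 clusters), against 2793 bp and 2470 bp for shared clusters. The highest-scoring cluster of replicate 2 as a whole, 2R from 1258458 to 1259952 (1495 bp, score 1.49), had no counterpart in replicate 1. Next among such clusters of replicate 2 were 2R from 17030250 to 17032716 (score 1.07, rank 20 in its list) and X from 11483469 to 11484969 (score 0.93, rank 84). In replicate 1 the highest were 2R from 2892732 to 2894367 (score 0.99, rank 75), X from 9994657 to 9996628 (score 0.98, rank 86) and X from 11636221 to 11637995 (score 0.94, rank 110). A cluster of the combined list overlapped each of these 6 regions.

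Domain lengths differed between the replicates. Replicate 1 had 316 clusters longer than 10 kb, which held 33.7% of its bases, and replicate 2 had 218, which held 21.2%. The longest cluster measured 74487 bp in replicate 1 and 49815 bp in replicate 2, while median lengths were 2140.5 bp and 2049 bp. The mean length was 3640 bp ± 472 (SD, n = 2).

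The second comparison set the combined list against the replicates. Combined clusters that overlapped a cluster in each replicate were longer at the median than the other classes. They numbered 2265 (30.1%, 95% exact interval 29.0 to 31.1), had a median length of 6015 bp and held 67.5% of the bases of the list. A further 908 overlapped replicate 1 alone and 1022 replicate 2 alone, with median lengths of 2038 bp and 1982 bp. The largest class, 3341 clusters (44.3%), overlapped neither replicate, had a median length of 1325 bp and held 16.9% of the bases. Longer combined clusters meet both lists more easily under the 1 bp rule, and chance overlap was not measured for this comparison. In the other direction 98.6% of the clusters of replicate 1 and 99.2% of those of replicate 2 overlapped a combined cluster. The shortest combined cluster was 1001 bp and the shortest replicate cluster 1301 bp, and all 7536 combined clusters began at an even coordinate, as did 2185 of 4370 in replicate 1. Scores were not compared between the combined list and the replicate lists.

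The 10 highest-scoring regions seen in both replicates lay on 2R (4 regions), 3L (2), X (2), 2L (1) and 3R (1) and spanned 6789 to 54647 bp, with combined scores of 1.07 to 1.44. First was 2R from 5428876 to 5456190, a domain of 27315 bp that was a single cluster in both replicates and the top-scoring cluster of replicate 1 (1.47). It was followed by 2R from 20201182 to 20224412 (23231 bp, combined score 1.16), 2L from 2748688 to 2756048 (7361 bp, 1.14) and X from 1856076 to 1892056 (35981 bp, 1.13). Next came 3L from 16030718 to 16044384 (13667 bp, 1.12), 2R from 16883098 to 16889886 (6789 bp, 1.09) and X from 2175514 to 2203712 (28199 bp, 1.08). The last of the 10 were 3L from 605130 to 650126 (44997 bp, 1.08), 3R from 12030842 to 12085488 (54647 bp, 1.07) and 2R from 19757214 to 19764108 (6895 bp, 1.07). Clusters of replicate 1 covered between 81.6% and 100% of each of these regions, and those of replicate 2 between 91.6% and 99.8%. Genes at these positions are not named, because no annotation of this build was used here.

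The 5 longest regions seen in both replicates were 62 to 119 kb domains that the replicates resolved into different numbers of pieces. The longest, 3L from 11325028 to 11443618 (118591 bp), was covered to 98.5% by 5 clusters of replicate 1 and to 84.9% by 17 clusters of replicate 2. On X from 19251804 to 19331878 (80075 bp), 8 clusters of replicate 1 covered 81.9% and 15 of replicate 2 covered 75.8%. The domain on 2L from 1400542 to 1480194 (79653 bp) held 7 and 8 clusters, covering 90.6% and 93.5%. That on 3R from 5694864 to 5772468 (77605 bp) held 1 and 7 clusters, covering 96.0% and 94.1%. That on 3L from 19139188 to 19201652 (62465 bp) held 2 and 5 clusters, covering 96.9% and 86.0%.

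**Figure D2:**
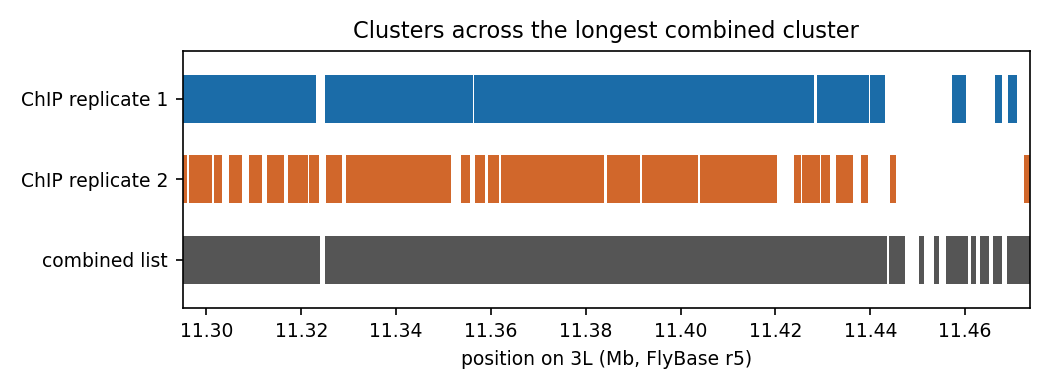
Clusters of both ChIP replicates and of the combined list (rows, boxes to scale) around the longest combined cluster, by position on 3L in Mb on FlyBase r5. The combined cluster from 11325028 to 11443618 is covered by 5 clusters of replicate 1 and by 17 shorter ones of replicate 2.

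The third comparison was between chromosomes. The large autosomal arms were covered to between 13.3% ± 0.745 (2L) and 16.0% ± 0.238 (2R), with 15.6% ± 1.52 on 3L and 13.6% ± 0.0337 on 3R (SD, n = 2 each). The X was covered to 11.6% ± 0.788, below each large autosomal arm in both replicates. The fourth chromosome, a small chromosome rich in repeats and heterochromatin proteins, was covered to 8.69% in replicate 1 and 4.66% in replicate 2. Heterochromatic and unplaced sequences together were covered to 0.0906% and 0.141%, with 21 and 35 clusters, and no cluster was called on YHet or Uextra in any of the 3 lists. That pooled share includes the long unplaced sequences Uextra (29004656 bp) and U (10049037 bp). Mappability was not measured for any of these sequences, so few clusters there do not show that the mark is absent. Among the heterochromatic sequences assigned to a chromosome, 2LHet was covered most in the replicates, to 1.00% in replicate 1 and 1.74% in replicate 2. These shares rest on 2 and 3 clusters. In the combined list XHet was covered most, to 6.67% by 8 clusters, against 2.22% for 2LHet.

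The ratio of the covered share of X to that of the autosomes was 0.80 ± 0.018 (SD, n = 2), with 0.81 in replicate 1 and 0.79 in replicate 2. Among the clusters scoring at or above the median of their list the ratio was 0.96, so X lay nearer to the autosomes among the higher-scoring clusters. Clusters on X had higher scores than those of the large autosomal arms. A cut at the median of the list therefore keeps a larger part of the X clusters, and the ratio of 0.96 is not separate evidence. The median score on X was 0.67 in replicate 1, where the medians of those arms lay between 0.59 and 0.60, and 0.62 in replicate 2, where they lay between 0.55 and 0.56. The difference of X from the large autosomal arms, taken within each list, was 0.07 ± 0.0077 (SD, n = 2), and within the combined list it was 0.05. The covered share was lower and the median score higher on X in both replicates, and no test was run on these values, since an exact paired permutation test over 2 replicates cannot give p below 0.5.

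On the fourth chromosome replicate 1 had 45 clusters and replicate 2 had 31. Of these, 24 in replicate 1 and 25 in replicate 2 overlapped the other list. The covered share was 1.86 times higher in replicate 1, whereas that ratio ranged from 1.00 to 1.15 over the other major arms. The fourth chromosome held 1.03% of all clusters of replicate 1 and 0.631% of those of replicate 2, a difference that did not pass Fisher's exact test on cluster counts after adjustment over the 6 major arms (two-sided, p = 0.0376, Benjamini-Hochberg adjusted p = 0.226). That test covers counting error only and compares these 2 lists.

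**Figure D3:**
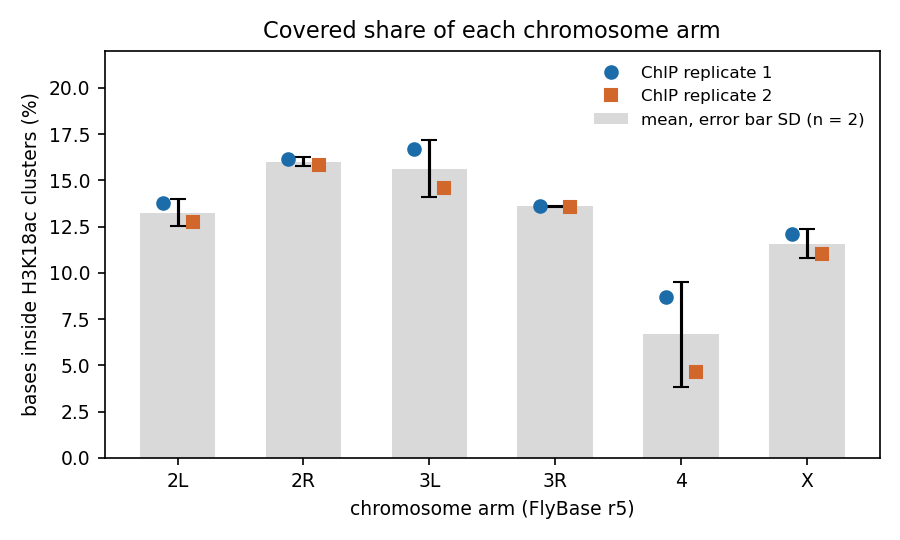
Percent of the bases of each major chromosome arm that lie inside H3K18ac clusters (vertical axis), by arm; bars are means with SD over 2 ChIP replicates and points are the replicates. X lies at 11.6% and below the large autosomal arms, and the replicates are farthest apart on the fourth chromosome, at 8.69% and 4.66%.

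Along the arms, coverage rose and fell in the same places in both replicates. Over 118 windows of 1 Mb the covered shares of the 2 replicates had a Pearson's r of 0.96 and a Spearman's rho of 0.94, across windows that are not independent replicates. The most covered window in both replicates was the first Mb of 3L (41.6% and 39.7%), followed by 2L from 14000001 to 15000000 (35.4% and 29.4%). By the mean of both replicates 2R from 2000001 to 3000000 came next (28.7% and 25.2%), close to 3R from 5000001 to 6000000 (27.9% and 25.2%) and 3L from 11000001 to 12000000 (28.9% and 23.1%). By the same mean the least covered were X from 21000001 to 22000000 (1.47% and 1.41%), 2L from 15000001 to 16000000 (1.36% and 1.90%) and 3L from 23000001 to 24000000 (1.93% and 1.86%). The median window was covered to 13.7%.

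The 1 Mb at the end of each arm sequence nearest the centromere was depleted on 4 of the 5 large arms. It was covered to 2.84% ± 0.984 on 2L, 2.90% ± 0.573 on 2R, 1.05% ± 0.304 on 3L and 2.81% ± 0.426 on X (SD, n = 2 each). The rest of the arm was covered to 13.7% ± 0.823 on 2L, 16.6% ± 0.278 on 2R and 16.3% ± 1.57 on 3L, and on X to 12.6% in replicate 1 and 11.4% in replicate 2. On 3R the same end was covered to 25.8% ± 0.873, above the 13.1% ± 0.00255 of the rest of that arm. These differences had the same direction in both replicates.

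The longest stretches of the major arms without a combined cluster were 3L from 23980655 to 24529635 (548981 bp), X from 21450245 to 21845111 (394867 bp) and 2L from 16884259 to 17221945 (337687 bp). The stretches on X and 2L held no cluster in either replicate. That on 3L held 1 cluster of replicate 1, with a score of 0.52, which covered 0.338% of it. Low mappability of repeats near centromeres can lower the number of clusters called there, and mappability was not measured here.

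**Figure D4:**
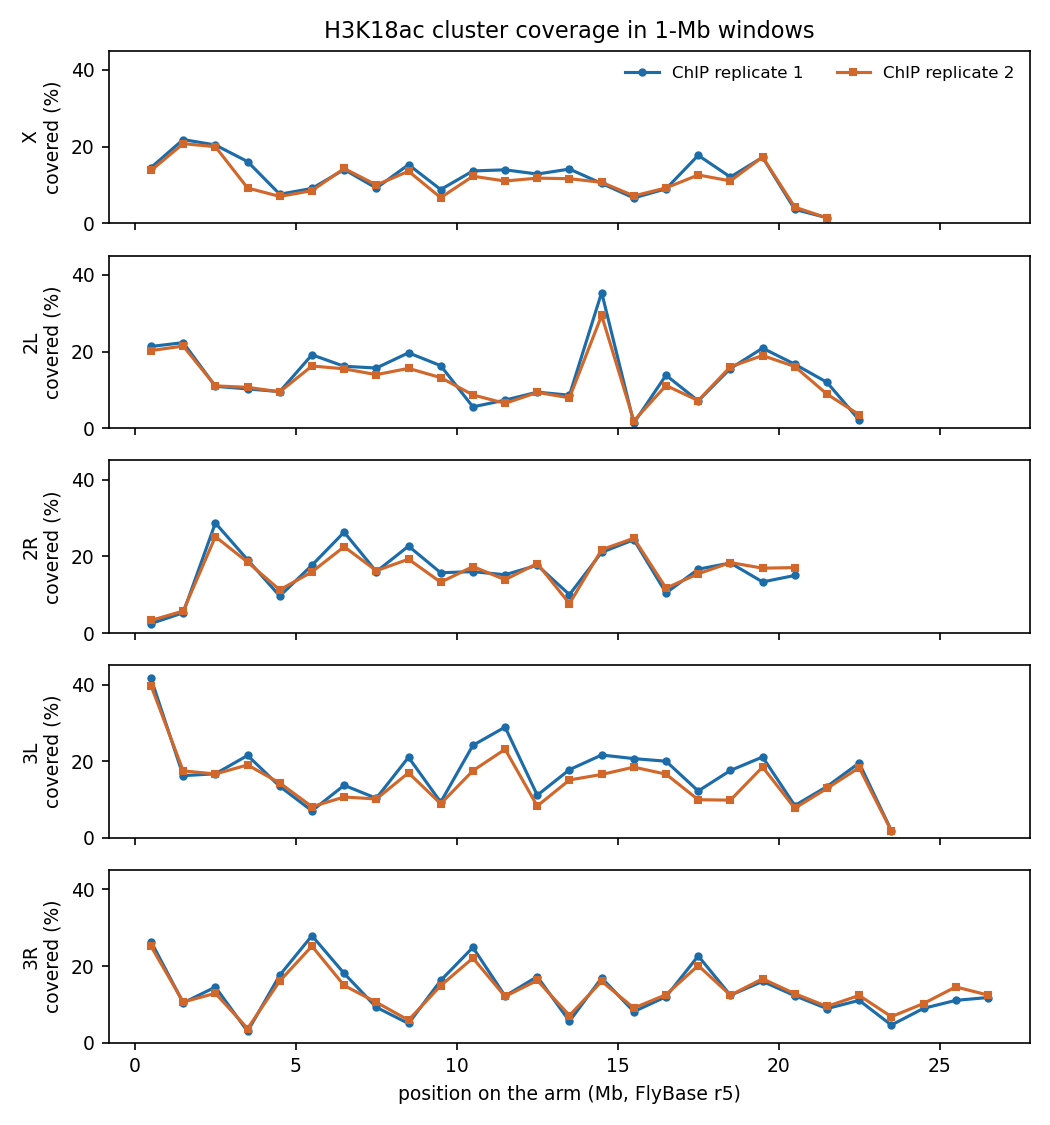
Percent of each 1-Mb window that lies inside H3K18ac clusters (vertical axis) by position in Mb on X and the large autosomal arms (FlyBase r5), as a line per ChIP replicate. Both lines reach their highest value in the first Mb of 3L, at 41.6% and 39.7%.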

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

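Chance sharing with rotations of 50 to 500 kb, sharing on the major arms alone and all values of the X score difference under other settings were chosen after seeing the data; the other alternatives were planned. Of 31 alternative values, 24 stayed the same and 7 moved; none reversed. A tested result stayed the same if it kept its direction and its side of the threshold, a number of clusters if within 1.5 times, the combined share if within its 95% exact interval, and other values if within 1 SD of the replicates. With 2 replicates, each always lies within 1 SD of their mean. Leaving out 1 replicate could therefore not move the X to autosome ratio or the X score difference. Those values count among the 24 but say nothing about robustness. Sharing of clusters between replicates ranged from 43.9% (reciprocal overlap of 50%) to 72.2%, and the Jaccard index from 56.3% to 59.1%, each with permutation p = 0.0001 against rotation. With rotations of 50 to 500 kb, chance sharing was 23.8% of clusters. With only clusters scoring at or above the median of their list, the mean number per replicate was 2320.5, which the choice itself sets, the covered length was 12.4 Mb in place of 16.8 Mb, and the X to autosome ratio was 0.963 in place of 0.80. Counted as clusters per Mb, that ratio was 0.911; the cause was not tested. With clusters within 1 kb merged, 36.6% of combined clusters overlapped both replicates in place of 30.1%. With 1 replicate left out, so that overlap with the other was enough, 42.1% to 43.6% did, since fewer overlaps were then required. For ChIP against input, no paired analysis was possible because the inputs enter only through the lists of enriched clusters and have no values of their own here; X and autosomes were compared within each library. Placement at transcription start sites and gene lists was not run. Unknown read depth limits every statement about clusters that were not called.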

Other observations

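The tests of X by calling floor and by length class, of whole-number score differences and of sharing by score were chosen only after the results they bear on, or related values, had been seen; the 50% bound on bridged gaps was written before those gaps were counted.

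Clusters lay closer together than random placement would give. The median distance between neighbouring clusters on the major arms was 4789 bp in replicate 1 and 4614 bp in replicate 2, against means of 16312 bp and 14669 bp in 1000 random placements of the same clusters. After merging of clusters within 1 kb the medians were 9522.5 bp and 9114 bp, against 21432 bp and 19395 bp.

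Close spacing may come from 1 domain split into pieces by the caller. If splitting were the whole cause and the other replicate kept such domains whole, over 50% of the gaps under 5 kb would lie inside a single cluster of it. The share was 22.2% for replicate 1 (95% exact interval 20.4 to 24.0) and 38.8% for replicate 2 (36.9 to 40.7), below the bound in both. Both replicates can break the same domain, as in the longest combined cluster with 5 and 17 pieces, so this test cannot decide on splitting. Counted afterwards, single clusters of the combined list bridged 56.6% and 62.7% of the same gaps. That list was made from the same libraries and covered more of the arms, and chance bridging was not measured. The count therefore cannot decide either, and splitting stays open. No biological explanation was tested.

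Clusters on X had higher scores although X was covered less. One candidate explanation is a raised calling floor on X, since male embryos carry fewer X copies, so that only stronger clusters pass. Suppose the floor only removed weaker clusters and strong sites were equally dense on X and the large autosomal arms. The number of high-scoring clusters per Mb would then be equal on both. The number above the 90th percentile of score was instead 1.74 times higher on X in replicate 1 (95% exact interval 1.40 to 2.15) and 1.51 times higher in replicate 2 (1.22 to 1.86). These intervals cover counting error only and treat clusters as independent, though clusters lay close together. A floor that only removes weaker clusters would not give these ratios if strong sites were equally dense on both. That density is unknown here, so the test cannot decide on a raised floor. Whether fewer X copies also change the spread of scores was not tested either, so a raised floor stays open with or without such a change. A chromosome-wide offset of the ChIP to input ratio on X stays open, as the X median was higher in each of 4 length classes in both replicates, by 0.055 or more. It cannot be told apart from more acetylation along X, because input values were not analysed here. Neither would by itself lower the covered share of X. That share was 0.81 times that of the autosomes in replicate 1 and 0.79 times in replicate 2.

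Many clusters were called in 1 list and not in another. Calls close to the threshold may account for part of those of a single replicate: the share without a counterpart was 6.17 times higher in the lowest than in the highest score quartile in replicate 1 (44.1% and 7.14%) and 7.03 times higher in replicate 2 (43.0% and 6.11%). The trend had the same direction at 2 to 4 kb and at 4 to 8 kb, but clusters under 2 kb made up 74.5% of those without a counterpart in replicate 1 and 81.6% in replicate 2, and among them the lower-scoring ones were shared more often, by 8.89 and 3.32 percentage points, the latter not past the threshold (Fisher's exact test, p = 0.121), so this explanation stays open for most of them. Among combined clusters, 14 scored above the best region seen in both replicates (1.44), up to 3.61 on 3R from 1984256 to 1985270; none of the 14 overlapped a replicate cluster, and 12 were shorter than any replicate cluster. A ratio of few reads may set these scores if their scale is log2, which is not stated: 8 of the 14 differed from another by a whole number of 1 or more (tolerance 1e-05), against at most 3, equal scores included, in 10000 random draws of 14 other combined clusters and at most 2 in draws with evenly spread fractional parts, and read counts were not analysed here.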
